A study of Homo sapiens with 2 samples.

How the data were processed

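Small RNA was sequenced from HTR-8/SVneo cells, a human trophoblast line immortalized with the SV40 T antigen, in 2 libraries. Per the labels, 1 library came from cells kept for 24 h with 10 ng/ml interferon-gamma (IFN-gamma) and 1 from control cells kept for 24 h in plain medium. The protocol shared by both samples names 4 h of starvation in plain medium, per the labels, and does not say separately whether the control cells went through it. Growth medium held 10% fetal bovine serum, RNA was isolated with Trizol, and 1 µg of total RNA entered the TruSeq Small RNA preparation, per the labels. Sequencing was on an Illumina Genome Analyzer IIx, per the series' design text. The groups follow the treatment label of each sample.

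Per the series' design text, the authors removed adapters and low-quality bases and counted reads against miRBase release 21 in CLC Genomics Workbench 6.5.1. The allowed mismatches and the treatment of reads that match several miRNAs are not given in the sources used here. The tables hold 4 kinds of value per miRNA. Read counts were deposited as whole numbers, per the file headers, with comma separators that were removed before use. Normalized values were deposited beside them, and dividing the count by the value showed that they are reads-per-million values (RPM) of the library's miRNA reads as the authors scaled them. A signed fold of normalized values, here treated as a score with no values between -1 and 1, was computed by the authors, with negative numbers where the untreated library was higher. A p-value per miRNA was also deposited by the authors, whose test and whose adjustment, if any, are not given in the sources used here. The columns carry library codes, and the match of each code to control or IFN-gamma comes from the tables' own names.

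The full table has 1035 rows, but its names cannot be used. Each of the 1034 rows after the first carries the previous row's number plus 1, from miR-6087 to miR-7121, as a spreadsheet fill would give. A shorter table deposited by the authors names 207 miRNAs. Each was joined to the full table by its fold and both counts, and 0 of the 207 matched more than 1 row, which left 828 rows without a name. The shorter table's title states a p-value of 0.05 and a fold of 2. In the authors' deposited table, however, 151 of the 207 miRNAs have a fold under 2, and the 207 are those with a p-value of at most 0.05. The authors chose them from these same libraries, so every statement on a named miRNA or a list covers only that selected set. The design had assumed a name for every row. Counts over all miRNAs still use all rows with reads.

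RPM were recomputed as the count divided by all miRNA reads of the library in the full table, 7156744 in the untreated and 2228769 in the IFN-gamma library. These are 99.98% and 99.99% of the totals implied by the authors' normalized values. Each ratio of RPM, IFN-gamma over untreated, has an exact 95% interval from the conditional binomial distribution of the count. PCR reads without molecular identifiers are not independent molecules, so these intervals cover counting error only. With 1 library per group no difference has a replicate check, no test between conditions could be made and no p-value was computed. A miRNA counted as 2-fold higher or lower when its log2 ratio with a pseudocount of 1 RPM was at least 1 in size, its interval excluded 1 and it had at least 50 reads in the 2 libraries together. Folds are printed as plain ratios of RPM, and log2 ratios include the pseudocount, which understates changes at low levels.

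Before the data were examined, 21 lists of miRNAs were fixed from textbook knowledge, covering inflammatory miRNAs, families, placental and imprinted clusters, and markers of other cell types. A list's median log2 ratio was set against 10000 random lists of the same size, drawn from the named miRNAs past the read minimum and matched on deciles of mean level. These percentiles describe the 2 libraries and are not tests. Lists with fewer than 3 members have values only. The rule for single miRNAs, fixed at the same time, takes the 10 highest and 10 lowest ratios among those counted as 2-fold different, the 8 most abundant, up to 3 most abundant members of each list, and miR-155-5p, miR-146a-5p and miR-21-5p. Of the 8 most abundant rows 2 have no name, so the 8 were taken among named miRNAs. Agreement of the 5p and 3p arms of a hairpin was described by Pearson's and Spearman's correlation across hairpins.

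The tables give no coordinates. Hairpin positions, host genes and GC content were taken by name from GENCODE release 29 (GRCh38), in which all 207 named miRNAs matched a hairpin. A near-identical relative was an 18-base stretch of the arm found with at most 2 mismatches in the same arm of a hairpin of another name, among 1880 hairpin genes. Only the same strand was searched, so hairpins that lie opposite each other were not matched. The count of such a miRNA is uncertain, since the authors' counting could split reads between the relatives. A structural RNA match was 18 bases shared with any of 5724 ribosomal, mitochondrial transfer, small nuclear, small nucleolar and other structural transcripts of the annotation. Most 18S and 28S ribosomal RNA sequences were not searched. Nuclear transfer RNAs were not searched at all, so the lack of a match says nothing about their fragments.

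The alternatives tried were scaling by trimmed mean of M-values (30% of ratios and 5% of levels trimmed at each end), scaling by median of ratios, totals without the 5 most abundant miRNAs, and the authors' normalized values. Pseudocounts of 5 and 0.1, no read minimum, a minimum of 200 reads, a 1.5-fold threshold, an interval excluding 1.5 and no interval criterion were also tried. Calling and intervals were tested on counts simulated with Poisson error only for the comparison of IFN-gamma with untreated, with 200 of 474 miRNAs altered. The intervals covered the true ratio in 94.7% of miRNAs, 78% of simulated 2.5-fold and 97% of simulated 4-fold differences were called, and 0% of the unaltered miRNAs were called. The simulation held no variation between cultures or library preparations. These figures therefore check the calculation and are not error rates for the real libraries. Python 3.11.15 was used with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.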

Results

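Mature miRNAs were counted in HTR-8/SVneo trophoblast cells kept for 24 h with IFN-gamma, a cytokine made by lymphocytes, and in untreated cells, with 1 library per group. The untreated library held 7156744 miRNA reads and the IFN-gamma library 2228769, a 3.21-fold difference in depth. Reads were found for 1014 miRNAs in the table, and 474 had at least 50 reads in the 2 libraries together. All 1014 had reads in both libraries, with 0 rows at 0 in 1 library only, despite the difference in depth. A miRNA seen in only 1 library therefore cannot appear among the differences. How the deposit treated such miRNAs is not known. The 5 most abundant rows took 35.7% of the untreated and 35.8% of the IFN-gamma reads. Named miRNAs carried 83.7% of the reads in each library.

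The comparison asks which miRNAs differ between IFN-gamma-treated and untreated trophoblast cells. Most of the miRNA pool was at similar levels in both. The large differences lay mostly among miRNAs of low or middle abundance, although let-7c-5p stood at 2630 RPM untreated. Of the 474 miRNAs past the read minimum, 21 were at least 2-fold higher and 27 at least 2-fold lower with IFN-gamma. By log2 ratio, the higher group was led by miR-6087, miR-3960 and miR-4792 and held the epithelial miR-205-5p. The lower group was led by let-7c-5p, miR-151b and miR-99a-5p. All 17 named members of the imprinted 14q32 cluster were lower. There was no replicate check for any of these differences, and the intervals given cover counting error only. The number of higher miRNAs depended on the read minimum, with 46 under no minimum and 12 at 200 reads, and at 1.5-fold 43 were higher and 75 lower.

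Across the 474 miRNAs, 342 (72.2%) lay within 1.5-fold of their untreated level. The median log2 ratio was -0.09, against -0.15 under trimmed-mean scaling and 0.023 over the 1014 miRNAs with no read minimum. Levels on the log2(RPM + 1) scale correlated between the libraries with a Pearson r of 0.95 and a Spearman rho of 0.93, across miRNAs, which are not independent replicates. The most abundant named miRNA was miR-21-5p, which is known as a growth-promoting miRNA and lies in an exon of VMP1 on chromosome 17. It stood at 103651 RPM untreated and 120278 RPM with IFN-gamma, 1.16-fold higher (95% interval 1.16 to 1.17). Among the other abundant miRNAs, miR-10a-5p was 1.44-fold higher (1.43 to 1.45), miR-16-5p 1.28-fold higher (1.27 to 1.29) and miR-26a-5p 1.19-fold higher (1.18 to 1.20). The ratio was 0.864 (0.859 to 0.868) for miR-22-3p and 0.851 (0.846 to 0.857) for miR-92a-3p. It was 0.908 (0.902 to 0.915) for let-7a-5p and 0.806 (0.799 to 0.813) for let-7f-5p. Apart from miR-21-5p and miR-22-3p, these abundant miRNAs have near-identical relatives, so their counts are uncertain.

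**Figure D1:**
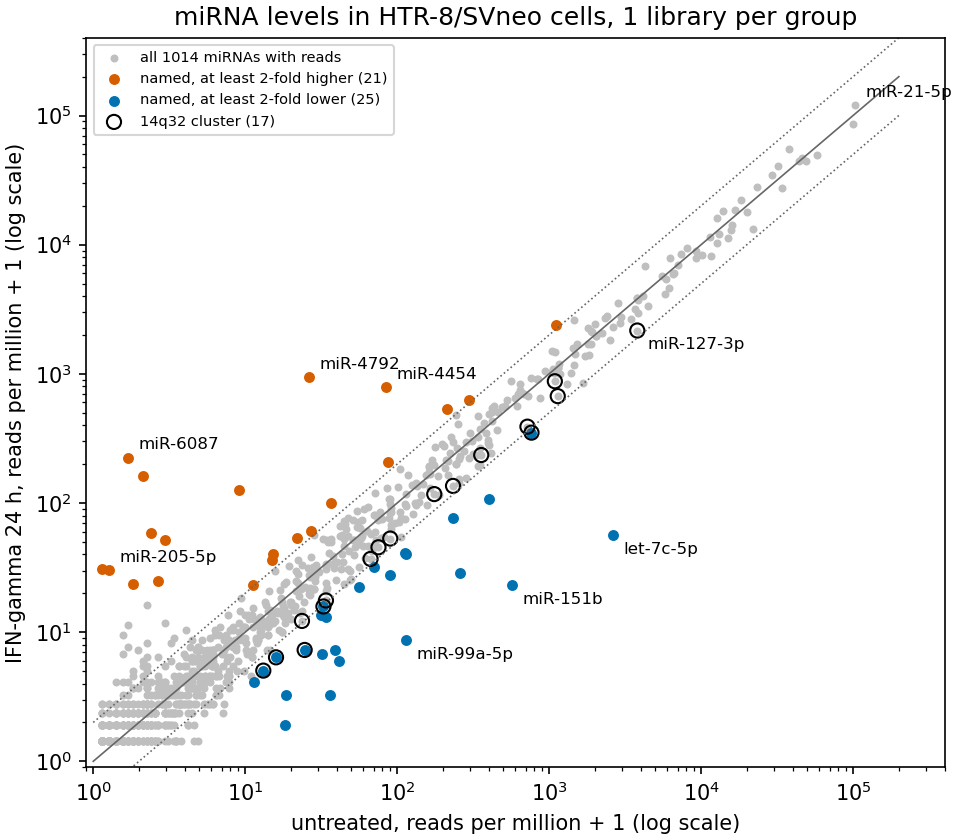
Reads-per-million values (RPM) plus 1 in the untreated (x axis) and IFN-gamma (y axis) libraries, both on log scales, with 1 point per miRNA for the 1014 miRNAs with reads. The solid line marks equal levels and the dotted lines a 2-fold difference; orange points are the 21 named miRNAs at least 2-fold higher, blue points the 25 named miRNAs at least 2-fold lower, and open circles the 17 members of the 14q32 cluster, all below the solid line.

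All 21 miRNAs that were at least 2-fold higher have names in the authors' selection. The most abundant of the 10 highest with IFN-gamma was miR-4792, with 180 untreated and 2089 IFN-gamma reads, or 25.2 and 937 RPM, 37.3-fold higher (95% interval 32 to 43.6). Its hairpin lies on the minus strand of chromosome 3 (24521362 to 24521435, GRCh38), outside annotated host genes. The highest ratio was that of miR-6087 (chromosome X, 109054542 to 109054590), with 5 untreated and 497 IFN-gamma reads, 0.699 against 223 RPM and a 319-fold ratio (136 to 987). Only 8 untreated reads were counted for miR-3960, whose hairpin overlaps an exon of CDK9, against 361 with IFN-gamma, a ratio of 145 (72.8 to 338). For miR-663a, 1 read stood against 67, a ratio of 215 with a wide interval of 37.3 to 8623. Since no row had reads in 1 library only, it is not known how far counts this low reflect the handling of zeros in the deposit. The epithelial miR-205-5p, a repressor of ZEB1 and ZEB2, lies in an exon of MIR205HG on chromosome 1 (209432133 to 209432242). It had 2 untreated and 65 IFN-gamma reads, a ratio of 104 (27.8 to 880). The ratio was 41.4 (21.8 to 88.4) for miR-3141, 25.9 (14.8 to 48.9) for miR-4634 and 26.8 (11.5 to 76.4) for miR-5787.

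Also higher were miR-7704, in an exon of HOXD1, at 15.5-fold (11.6 to 20.9), and miR-4454, with 83.6 and 791 RPM, 9.47-fold higher (8.62 to 10.4). The ratios of the other 11 lay between 2.12 for miR-1260b and 14.2 for miR-4516. The most abundant of them was miR-1307-5p, named after its values were seen, with 1110 RPM untreated and 2393 RPM with IFN-gamma, 2.16-fold higher (2.08 to 2.23). Hairpin GC content was high in this group, with a median of 56.4% against 50.8% in the other 178 named miRNAs past the minimum, and 9 of the 21 hairpins had at least 65% GC. These 9 had the largest ratios, all at or above that of miR-4516, a level shared only by miR-205-5p, at 48.2% GC. Near-identical relatives make the counts of miR-6087, miR-3960, miR-663a, miR-5787, miR-4454, miR-4516, miR-1246, miR-1260a, miR-1260b, miR-33a-5p and miR-34c-5p uncertain, which are 11 of the 21.

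Of the 27 miRNAs that were at least 2-fold lower, 25 have names. The largest difference was that of let-7c-5p, a member of the growth-repressing let-7 family, with 18825 untreated and 123 IFN-gamma reads. It stood at 2630 RPM untreated and 55.2 RPM with IFN-gamma, 47.7-fold lower (95% interval 39.9 to 57.4). Its hairpin lies in an intron of MIR99AHG on chromosome 21 (16539828 to 16539911), beside that of miR-99a (16539089 to 16539169). For miR-99a-5p, 810 untreated and 17 IFN-gamma reads were counted, 14.8-fold lower (9.21 to 25.6). The same host gene holds miR-125b-2 (16590237 to 16590325), whose 3p arm, named after its values were seen, was 2.91-fold lower (2.33 to 3.67). For miR-151b, 566 RPM untreated stood against 22.0 RPM with IFN-gamma, 25.8-fold lower (19.5 to 34.9).

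Of the rarer members of the miR-378 family, miR-378d was 9.31-fold lower (7.23 to 12.2) and miR-378e 6.07-fold lower (3.56 to 11.3). The far more abundant miR-378a-3p, named after its values were seen, stood at 5838 RPM untreated and had a ratio of 0.926 (0.908 to 0.945). In the miR-320 family, miR-320d was 15.6-fold lower (6.61 to 48.6) and miR-320c 8.15-fold lower (4.49 to 16.5). Lower counts were also found for miR-7-5p, a repressor of EGFR, at 5.32-fold (3.05 to 10.1), and for miR-18b-5p at 7.79-fold (3.25 to 24.4). For miR-1297, 123 untreated and 2 IFN-gamma reads gave 19.2-fold (5.19 to 160). Each of the 10 lowest ratios belonged to a miRNA with a near-identical relative, so these counts are uncertain where the authors' counting could move reads between relatives. In all, 19 of the 25 named miRNAs in this group had such a relative, and 6 had none in the search, which covered the same strand only. Among the 6, miR-3529-3p, named after its values were seen, was 3.08-fold lower (2.63 to 3.64). Its hairpin lies on the minus strand of chromosome 15 (88611847 to 88611924). This is within the span of a plus-strand hairpin of miR-7-5p (88611825 to 88611934). Whether miR-3529-3p shares reads with miR-7-5p was not tested.

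The 14q32 cluster is an imprinted miRNA cluster expressed from the maternal chromosome and abundant in placenta. Its 17 named members, from 14 hairpins on the plus strand of chromosome 14 (100869060 to 101065991, a span of 197 kb), were all lower. Their median log2 ratio of -0.86 lay at percentile 0.735 of random lists of named miRNAs at matched levels, whose medians ran from -0.76 to 0.39 in 95% of draws. The most abundant member was miR-127-3p, with 3799 RPM untreated and 2164 RPM with IFN-gamma, a ratio of 0.570 (0.552 to 0.587). The ratio was 0.590 (0.558 to 0.623) for miR-654-3p and 0.804 (0.765 to 0.845) for miR-411-5p. Named after their values were seen, the 5 members that were at least 2-fold lower were miR-409-3p, miR-409-5p, miR-432-5p, miR-380-3p and miR-487a-3p. Log2 ratios ran from -1.76 for miR-487a-3p to -0.31 for miR-411-5p. Host transcripts of these hairpins included introns of MEG8, MIR381HG and MEG9. Among the members, 10 have near-identical relatives.

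**Figure D2:**
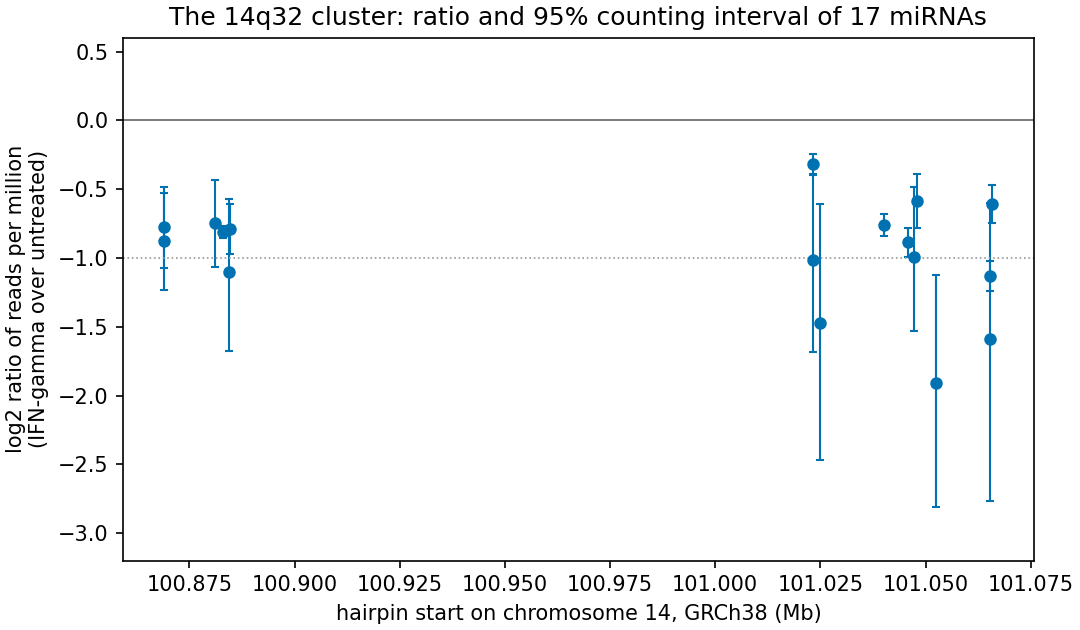
Log2 ratio of RPM, IFN-gamma over untreated and without a pseudocount, of the 17 named 14q32 miRNAs (y axis) against the start of their hairpin on chromosome 14 in Mb (x axis, GRCh38). Each point is 1 mature miRNA in 1 pair of libraries and each bar its 95% counting interval; the solid line marks equal levels, the dotted line a 2-fold lower level, and all 17 intervals lie below the solid line.

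Inflammatory miRNAs went both ways. Of the 7 named members of this list, 4 were higher and 3 lower, and the median log2 ratio of 0.21 lay at percentile 86.5 of its random lists. The NF-kB-induced miR-155-5p stood at 6486 RPM untreated and 5938 RPM with IFN-gamma, a ratio of 0.915 (0.898 to 0.933). The other strand product of the miR-21 hairpin, miR-21-3p, was 1.30-fold higher (1.29 to 1.32). For miR-146a-5p, a feedback inhibitor of Toll-like receptor signalling, 493 reads stood against 69, 2.23-fold lower (1.73 to 2.91). Its near-identical relative miR-146b-5p, named after its values were seen, was 1.18-fold higher (1.11 to 1.26). In the miR-29 family, which targets collagen mRNAs, miR-29a-3p had a ratio of 0.953 (0.938 to 0.968) and miR-29b-3p was 1.31-fold higher (1.23 to 1.40). As miR-29a-3p and miR-29b-3p are near-identical to each other, their counts are uncertain.

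The growth-linked families were mixed. Among 12 let-7 and miR-98 miRNAs, 4 were higher and 8 lower, with a median log2 ratio of -0.25 at percentile 24.0, and let-7i-5p was 1.22-fold higher (1.21 to 1.24). Among 11 miRNAs of the MYC-driven miR-17-92 cluster and its paralogs, 2 were higher and 9 lower, with a median of -0.40 at percentile 12.1. Their ratios were 0.939 (0.912 to 0.966) for miR-93-5p and 0.721 (0.697 to 0.746) for miR-20a-5p. In the miR-15/16 family, which represses cyclins and BCL2, 5 of 8 were higher and 3 lower, with a median of 0.26 at percentile 82.8. There miR-15b-5p was 1.13-fold higher (1.08 to 1.17) and miR-15a-5p 1.31-fold higher (1.24 to 1.38). Both named members of the p53-induced miR-34 family were higher, miR-34a-5p 1.61-fold (1.34 to 1.91) and miR-34c-5p 2.74-fold (2.03 to 3.68). The hypoxia-induced miR-210-3p, in an intron of MIR210HG, stood at 241 RPM untreated and 475 RPM with IFN-gamma, 1.97-fold higher (1.82 to 2.13).

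Among the miR-99, miR-100, miR-125 and miR-10 families, 6 of 12 were higher and 6 lower, with a median log2 ratio of 0.07 at percentile 88.0. The HOX-cluster miR-10b-5p was 1.20-fold higher (1.19 to 1.21), and miR-100-5p had a ratio of 0.606 (0.598 to 0.613). Of the 4 miRNAs of the miR-221 and miR-222 locus on chromosome X, 3 were lower, with ratios of 0.824 for miR-221-3p, 0.698 for miR-222-3p and 0.757 for miR-221-5p. The fourth, miR-222-5p, named after its values were seen, was 2.25-fold higher (1.79 to 2.83), and the list's median of -0.34 lay at percentile 28.5. In the miR-23/27/24 clusters 1 of 5 was higher and 4 lower, with a median of -0.23 at percentile 34.2. There miR-27b-3p was 1.27-fold higher (1.25 to 1.28), against ratios of 0.851 for miR-27a-3p and 0.933 for miR-23a-3p. In the miR-30 family 3 of 5 were higher, with a median of 0.15 at percentile 68.2. Its most abundant member, miR-30d-5p, was higher by 1.11-fold (1.10 to 1.13). In the miR-181 family 5 of 6 were higher, with a median of 0.21 at percentile 81.8. Its most abundant member, miR-181a-5p, was higher by 1.16-fold (1.14 to 1.18). The 3 other scalings lowered the list medians by nearly the same amount for each list, and the median closest to 0, that of the miR-99, miR-100, miR-125 and miR-10 families, was as low as 0.012. Near-identical relatives leave counts uncertain for 11 of the 12 let-7, 6 of the 11 miR-17-92, 4 of the 8 miR-15/16, 5 of the 5 miR-23/27/24, 4 of the 5 miR-30, 5 of the 6 miR-181 and 9 of the 12 miR-99, miR-100, miR-125 and miR-10 miRNAs.

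Markers of other cell types were few among the named miRNAs. The blood cell marker miR-486-5p stood at 1463 RPM untreated and 2595 RPM with IFN-gamma, 1.77-fold higher (1.72 to 1.83), while miR-486-3p had a ratio of 0.645 (0.547 to 0.757). The endothelial miR-126-5p was 1.34-fold higher (1.29 to 1.40) and miR-126-3p 1.27-fold higher (1.14 to 1.41). The neural miR-128-3p had a ratio of 0.854 (0.815 to 0.895). The lists of the chromosome 19 placental cluster, the miR-371 to miR-373 cluster, the epithelial miR-200 family, muscle, and fibroblast and smooth muscle had no member among the named miRNAs, and their levels were not analysed here.

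**Figure D3:**
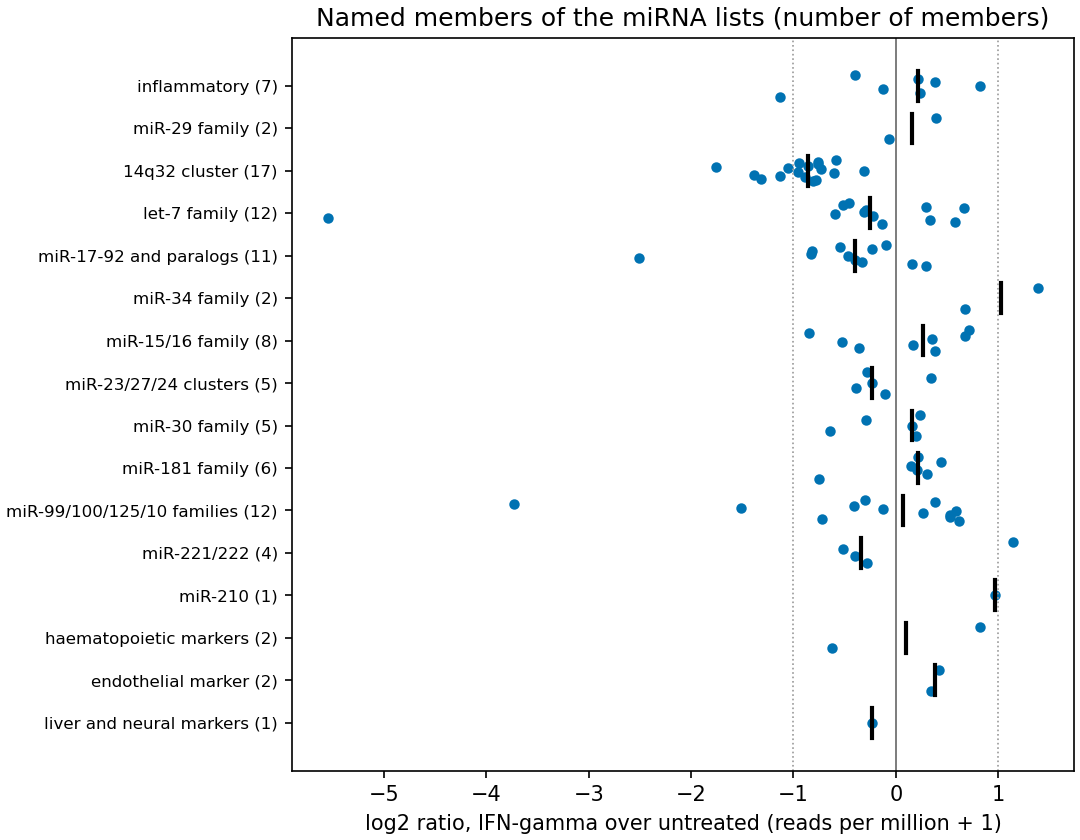
Log2 ratio of RPM plus 1, IFN-gamma over untreated (x axis), of each named member of 16 miRNA lists (y axis, number of members in brackets). Points are single miRNAs from 1 library per group, black bars list medians, the solid line equal levels and the dotted lines a 2-fold difference; the 14q32 cluster lies wholly below 0 and the other large lists fall on both sides.

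The 5p and 3p arms of 1 hairpin come from the same precursor. For 28 hairpins with both arms named and past the read minimum, the log2 ratios of the arms correlated with a Pearson r of 0.32 and a Spearman rho of 0.38, across hairpins, which are not independent replicates. Without the 2 hairpins farthest from the median of the 5p arm, r was 0.32. Both arms were lower in 10 hairpins and higher in 9, and the arms went opposite ways in the other 9. Without the 14q32 hairpins r was 0.14.

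In the authors' deposited table, 91 of the 207 selected miRNAs were higher and 116 lower with IFN-gamma. A fold of at least 2 was given there for 56 of them, 30 higher and 26 lower. The smallest fold in the authors' deposited table was 1.05, and 148 p-values were printed as 0. Another 204 rows past 2-fold had a p-value over 0.05 in the authors' deposited full table. The authors' deposited folds differed from the ratio of RPM by more than 5% in 0 of the rows compared. Of the 207, 199 had at least 50 reads, and intervals excluded 1 in all 199, with 83 higher and 116 lower, so among these named miRNAs an interval that excludes 1 adds nothing to the authors' selection. Among the 275 rows past the minimum without a name, 71 had intervals excluding 1, and 2 were at least 2-fold lower.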

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

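With 1 library per group no replicate could be left out. No paired analysis was possible because each group has 1 library. The counts of 21 higher and 27 lower miRNAs stayed within 1.5 times under the other scalings (20 to 21 higher, 29 to 35 lower), pseudocounts of 5 and 0.1 (20 and 23 higher, 21 and 31 lower), the authors' normalized values (21 and 27), an interval excluding 1.5 (20 and 24) and no interval criterion (21 and 27). Trimmed-mean scaling kept 20 of the 21 and all 27. The number of higher miRNAs was 46 with no read minimum and 12 with a minimum of 200 reads, against 36 and 19 lower. These settings compared 1014 and 331 miRNAs, all with reads in both libraries. At a 1.5-fold threshold 43 were higher and 75 lower. The median log2 ratio was -0.15 under trimmed-mean scaling and 0.023 with no read minimum, against -0.09, and the cause of the latter was not tested. Chosen after seeing the data, leaving out miRNAs with near-identical relatives left 6 of 25 named lower miRNAs, and leaving out hairpins of at least 65% GC left 12 of 21 higher ones. Likewise chosen after seeing the data, leaving out miRNAs matching a structural RNA left 20 of the 21 named higher miRNAs, and leaving out the 14q32 cluster left 20 of the 25 named lower ones. With 200 reads per arm the arm correlation was 0.20. Of the list medians under the other scalings, pseudocounts and read minimums, 36 moved by more than the counting error of the list's summed reads and 76 did not, and of the log2 ratios of miRNAs named by rule, under the other scalings and pseudocounts, 83 moved beyond their counting interval and 232 did not. Of the medians and log2 ratios recomputed, only the overall median with no read minimum changed sign. Few reads limit ratios in both libraries. With IFN-gamma, let-7c-5p rests on 123 reads and miR-1297 on 2, and in the untreated library miR-663a rests on 1 and miR-6087 on 5.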

Other observations

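Several related miRNAs outside the lists, named after their values were seen, went the same or opposite ways. The intronic miR-33a-5p of SREBF2 and miR-33b-5p of SREBF1, both repressors of the cholesterol exporter ABCA1, which are near-identical to each other, were 2.53-fold (95% counting interval 1.97 to 3.24) and 1.69-fold (1.45 to 1.962) higher with IFN-gamma. Both arms of miR-335, in an intron of the imprinted gene MEST, were higher, miR-335-3p 1.59-fold (1.56 to 1.62), at 4289 RPM untreated and 6835 RPM with IFN-gamma, and miR-335-5p 1.44-fold (1.38 to 1.499). In the miR-192/194/215 group, known from liver, gut and kidney, miR-192-5p was 1.28-fold (1.25 to 1.30) and miR-194-5p 1.27-fold (1.16 to 1.39) higher, whereas miR-215-5p, a near-identical relative of miR-192-5p, had a ratio of 0.605 (0.537 to 0.679).

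The sensory-organ pair miR-182-5p and miR-183-5p had ratios of 0.891 (0.880 to 0.902) and 0.911 (0.879 to 0.945). In the family of miR-130 and miR-301, the 3p arms of miR-130a, miR-130b, miR-301a and miR-301b were 1.15-fold, 1.11-fold, 1.22-fold and 1.40-fold higher. Each of these 3p arms has a near-identical relative within the family, and miR-182-5p and miR-183-5p are near-identical to each other. Their counts are therefore uncertain. Opposite to its 3p arm, miR-301a-5p was 2.45-fold lower (1.65 to 3.77). The arms of 1 hairpin also went opposite ways for miR-222 (log2 ratio 1.14 for 5p and -0.52 for 3p), miR-486 (0.83 and -0.63) and miR-100 (-0.72 and 0.62).

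Of the tests that follow, those of the whole 14q32 locus, of culture or preparation differences, of the chromosome 21 hairpins and of rarer near-identical miRNAs were chosen only after the results were seen. The 14q32 cluster was lower in all 17 of 17 named members, where the shared direction carries the information, since the authors' selection left only named miRNAs whose intervals exclude 1 among those past the read minimum. Hairpin GC content was argued against as the whole cause: after removing a slope of 0.62 log2 units per 10% GC the cluster's median was -0.83 (before, -0.86), at percentile 0.38 of random lists with a 95% range of -0.62 to 0.44. This covers GC content of the whole hairpin only. GC content of the sequenced mature miRNA was not measured, so a bias tied to it was not checked. Lower output of the whole locus with IFN-gamma is a candidate explanation that these 17 members allow. They cannot speak for the whole locus, since any member outside the authors' selection has no name here and was not seen. With 1 library per group, lower output cannot be told apart from a difference between cultures or library preparations that has nothing to do with IFN-gamma.

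Of the 2-fold lower miRNAs 76.0% (19 of 25) had near-identical relatives, against 53.4% (93 of 174) of the other named miRNAs. The share of the lower group was above that of 97.4% of random lists but at the upper end of their 95% range (40% to 76%). Names without an arm ending were searched over the whole hairpin, which can raise such a share. Whether reads moved between relatives in the counting therefore stays open. As a share of let-7a-5p, let-7c-5p was 5.37% untreated and 0.124% with IFN-gamma, and miR-151b was 4.32% and 0.183% of miR-151a-5p. In contrast, let-7d-5p was 5.93% and 5.61% of let-7a-5p and miR-181c-5p 8.75% and 8.76% of miR-181a-5p. Steep falls were also seen for miR-99a-5p (0.517% to 0.0575% of miR-100-5p) and miR-378d (4.44% to 0.514% of miR-378a-3p). Among the 19 rarer miRNAs described below, the steepest rise was smaller, that of let-7b-5p from 3.69% to 5.13% of let-7a-5p. From the same chromosome 21 host as let-7c-5p and miR-99a-5p, miR-125b-2-3p was only 2.91-fold lower (2.33 to 3.67), outside both their intervals. The intervals of the neighbours let-7c-5p (39.9 to 57.4) and miR-99a-5p (9.21 to 25.6) did not overlap each other either. Overlapping folds, predicted if lower transcription of the host were the whole cause, were thus not seen. The intervals cover counting error only and are narrow for such a comparison. Mature levels cannot decide on transcription, however, since the arms of 1 hairpin went opposite ways in 9 of 28 hairpins. Whether reads of an abundant miRNA were counted under a rarer relative is open as well. Rarer miRNAs were those with a named near-identical relative of at least 5 times their reads. The median log2 ratio of 19 such miRNAs was -0.46, at percentile 6.03 (95% range -0.49 to 0.34), and 7 of them were 2-fold lower. Having no such named relative, miR-320d, miR-320c and miR-1297 were left out. An effect of IFN-gamma on single miRNAs of this group also stays open and was not tested.

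The 2-fold higher miRNAs had GC-rich hairpins, with a median of 56.4% at percentile 99.1 of random lists of the same size (46.3% to 54.3%). At least 65% GC was found in 9 of 21 against 14 of 178. A GC-dependent difference between the library preparations may therefore explain part of the group, including most of its largest ratios. The comparison was planned without a match on level, and the 9 GC-rich members had only 1 to 180 untreated reads. GC content and low untreated level were thus not separated. GC content of the mature miRNAs, which are what was sequenced, was not measured. The other 14 GC-rich miRNAs had a median log2 ratio of 0.44, and 9 of them were higher. Fragments of structural RNAs stay open: 4.76% (1 of 21, miR-1246, which shares bases with a U2 small nuclear RNA) matched one, against 1 of 178 others. However, most 18S and 28S sequences and all nuclear transfer RNAs were left out of the search. An effect of IFN-gamma remains open too. For miR-205-5p, whose hairpin has 48.2% GC and no structural match, neither of these technical explanations was shown, but it rests on 2 untreated reads. Nor was either shown for other members under 65% GC without a structural match, such as miR-34c-5p (40.3% GC) and miR-338-3p (46.3% GC).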
